A study of Mus musculus with 46 samples.

How the data were processed

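Gene expression was measured in whole liver of male CB6F1 hybrid mice of 2 ages, 5 to 6 months (young) and 25 to 27 months (old). The young and old mice came from different suppliers, per the labels' protocols, so age and supplier could not be separated. Livers were taken without surgery (0 h) or at 0.5, 1, 2 or 4 h after removal of 70% of the liver (partial hepatectomy, PH) or after a sham operation. Surgery was done under injected and inhaled anaesthesia, per the labels' protocols. Total RNA was isolated on silica columns and biotin-labelled cRNA was hybridised to the Affymetrix Murine Genome U74 version 2 array, per the labels' protocols and the series' design text. The deposited values are log2 expression values made by RMA, per the submitters' processing notes. RMA normally corrects the background, normalises the probe intensities to 1 common distribution and combines the probes of a probe set. Its version, its software and which arrays were normalised together are not given in the sources used here. The 46 array medians lay between 6.22 and 6.33 on the log2 scale, and no value was transformed further. For arrays no read depth exists, and the number of arrays limits the precision.

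The 46 arrays form 18 groups of age, operation and time. Each 0 h and PH group has 3 arrays and each sham group has 2. The labels call these arrays replicates without saying that each came from its own animal, so the p-values measure the spread between these arrays, which may be partly technical. No 2 columns were identical, and the smallest median absolute difference between any 2 arrays was 0.0858 on the log2 scale. Same-numbered replicates of different groups did not deviate together: the mean correlation of their deviations was 0.00600, against -0.00287 for different numbers. In only 13 of 153 pairs of groups did every same-numbered pair exceed 0.1, so the numbers were not taken as pairs.

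The table held 12488 probe sets, of which 66 control probe sets were left out of the tests and 12422 were tested. By the platform annotation supplied with the data, 10833 of the tested probe sets carried 1 gene symbol, 396 carried several and 1193 were unnamed. Symbols were compared with a gene table through gene identifiers, and 0 changed. The 16 probe sets whose identifier was not in that table kept their symbol. The named probe sets covered 8251 symbols, 2073 of them with several probe sets. No gene was named from a probe set with several symbols.

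All 46 arrays entered 1 linear model with a mean for each of the 18 groups (limma 3.58.1 in R 4.3.3, lmFit and eBayes). The model left 28 residual degrees of freedom and the moderated variances added 5.09 prior degrees of freedom. Each comparison was a contrast of group means, adjusted by the Benjamini-Hochberg method over the 12422 probe sets, and passed at an adjusted p under 0.05. Values are log2 differences ± the standard error of the difference unless stated otherwise. The comparisons, tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined. The comparisons were PH with sham and sham with 0 h over both ages, PH with 0 h in each age, old with young at 0 h and over all conditions, and 2 F tests of an age difference in the PH response. The following sets of contrasts were added after the data had been seen. They are PH with 0 h as the mean of both ages, the sham change since 0.5 h, and the change since 0.5 h in the difference between PH and sham. The age difference in the PH change against 0 h at each single time was also added then.

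A set of 33 gene lists covering pathways, hepatocyte functions and markers of other liver cell types was fixed beforehand, with 3 of their symbols having no current symbol. Each list was tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the data. A list test used 1 probe set per gene, the one with the highest mean over the 46 arrays, and was adjusted over the 33 lists of a comparison. For the genes named, the rule took up to 10 of the highest and 10 of the lowest passing genes of a comparison, and up to 4 passing members of each list described. It gave up to 2 members as values where no member of a list passed, and up to 10 genes with the smallest adjusted p of each F test. Myc, Fos, Jun, Ccnd1, Cdkn1a, Cebpa, Cebpb, Cebpd, Socs3, Saa2, Pck1, Cyp7a1, Hgf and Igfbp1 could be named in any comparison. A gene with several probe sets was given by the one with the highest mean, and the text says where its other probe sets differed. Genes named because a count was 5 or less, or because a probe set had been singled out, were chosen after their values were seen.

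The alternatives were centring each array on its median, leaving out the dimmest 25% of probe sets, eBayes with trend and robust settings, and a fit of the compared groups alone. Others were 1 probe set per gene, probe sets with a cross-hybridisation suffix left out, the replicate number as a block, array weights, and each array left out in turn. Added after the data had been seen were the mean signal of the bacterial spike-in probe sets as a covariate, 2 arrays left out together, and the age comparison without the sham arrays. Where leaving out 1 array reduced a group to a single array, that array was assumed to vary like the other groups. The test was checked on simulated data in which 200 of the 12422 probe sets were changed. For PH with sham at 4 h, it recovered 85.1% of changes of 0.5 log2 units and 100% of changes of 2 log2 units, with 12 false calls. For PH with 0 h in young livers at 1 h, it recovered 61.2% of changes of 0.5 log2 units and 94.0% of changes of 1 log2 unit. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.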

Results

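The study followed gene expression in mouse liver during the first 4 h of regeneration and asked, per its design text, how the response to partial hepatectomy compares in young and old animals. Partial hepatectomy (PH) removes 70% of the liver, after which the remnant grows back. Of the 46 arrays, 6 came from livers at 0 h, 24 from livers after PH and 16 from livers after a sham operation, in which the liver is not removed. Each age had 3 arrays at 0 h, 3 at each of the 4 times after PH and 2 at each of the 4 times after sham surgery. Comparisons over both ages therefore rest on 6 PH, 6 control or 4 sham arrays per time. Replicates of a group correlated closely, with a median of 0.993 within groups and a range of 0.941 to 0.997 over all pairs of arrays. The median standard deviation between replicates was 0.139 on the log2 scale.

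The arrays differed in 3 measured ways. The 16 sham arrays lay apart from the other 30 on the first principal component, which held 26.8% of the variance: their scores ran from 7.75 to 30.3, and the highest other score was 6.27, in young 0 h replicate 3. The sham arrays were also alike in the bacterial spike-in probe sets, which report labelled bacterial transcripts added to the hybridisation mix, and whose mean was 9.42 ± 0.11 (SD, n = 16), against 9.74 ± 0.70 (SD, n = 6) at 0 h. In the 12 PH arrays of 1 and 2 h the spike-in mean was 8.33 ± 0.46 (SD), a difference of -1.41 from 0 h (exact permutation p = 0.000269, adjusted p = 0.00404), while in the PH arrays of 0.5 and 4 h it was 9.82 ± 0.80 (SD, n = 12). This grouping of times was not among the comparisons fixed beforehand and matches the levels tested. The p-value is therefore descriptive. Old PH 0.5 h replicate 3 had the lowest value, 7.68. Young 0 h replicate 3 had a beta-actin 3′ control signal of 10.8, against 12.5 to 12.7 in the other 0 h arrays. That control signal was 11.6 in the sham arrays and 12.3 at 0 h, a difference of -0.69 (exact permutation p = 0.00523, adjusted p = 0.0392).

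**Figure D1:**
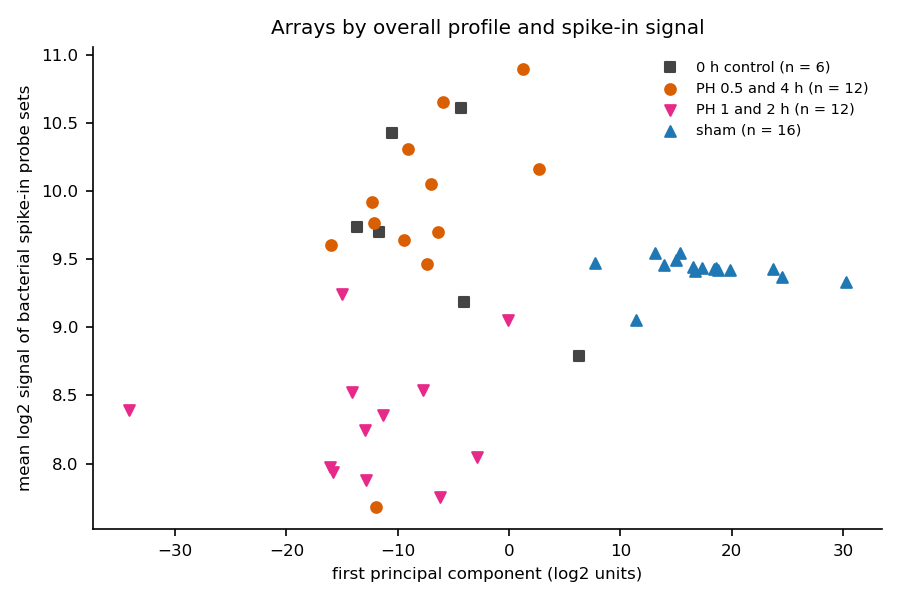
Each point is 1 array, with the mean log2 signal of the spike-in probe sets against its score on the first principal component, marked by operation. The 16 sham arrays score 7.75 or more and every other array 6.27 or less, and the PH arrays of 1 and 2 h have spike-in means of 7.76 to 9.25.

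At 0.5 h after PH, the immediate early transcription factor gene Jun was higher than at 0 h in the mean of both ages, by 0.97 ± 0.16 log2 units (n = 6 and 6 arrays, limma adjusted p = 0.00397). Slc25a25, a mitochondrial ATP-Mg/phosphate carrier, rose by 1.03 ± 0.18 (adjusted p = 0.00918) and Gjb2, the gap junction protein connexin 26 of hepatocytes, by 0.70 ± 0.13 (adjusted p = 0.00918). Igfbp1, an insulin-repressed hepatocyte gene for a binding protein of insulin-like growth factors, rose by 1.91 ± 0.41 (adjusted p = 0.0482), by 1 of its 2 probe sets. In all, 10 probe sets were higher and 1 was lower. Jun stayed past the threshold in each of the 12 fits without 1 array, with a highest adjusted p of 0.0243. Igfbp1 passed in 3 of 12, those without young 0 h replicate 2, old 0 h replicate 1 or old PH replicate 2, and its difference ranged from 1.54 to 2.49. Its call was also lost with median centring (adjusted p = 0.0548), trend and robust settings (0.118), the replicate block (0.0592) and 2 arrays left out together (0.233). Slc25a25 lost its call without old 0 h replicate 2 (0.93, adjusted p = 0.058) or replicate 3 (0.97, adjusted p = 0.0529), and Gjb2 without old 0 h replicate 3 (0.67, adjusted p = 0.0529). When the compared groups alone were fitted, 0 probe sets passed (Jun adjusted p = 0.108). The count of 11 became 4 without young 0 h replicate 1, old 0 h replicate 2 or young PH replicate 3. It became 7 without young 0 h replicate 2 or young PH replicate 1, 2 without old 0 h replicate 3 and 22 without old PH replicate 2.

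At 1 h after PH, Fos rose by 4.41 ± 0.65 log2 units in the mean of both ages (n = 6 and 6 arrays), with 1 of its 2 probe sets past the threshold. Atf3, a stress-induced transcription factor, rose by 3.37 ± 0.39 (2 of 3 probe sets), Egr1 by 2.24 ± 0.40 (1 of 2 probe sets), Nr4a1 by 2.00 ± 0.26, Jun by 1.51 ± 0.16, Dusp1 by 1.34 ± 0.29 and Myc by 1.19 ± 0.27. The metal-binding metallothioneins Mt2 and Mt1 rose by 4.40 ± 0.56 and 4.05 ± 0.60. Igfbp1 rose by 4.04 ± 0.41 (1 of 2 probe sets). The hepatocyte transcription factor genes Foxa2 and Hhex both fell by 1.11, with standard errors of 0.12 and 0.22. The highest limma adjusted p among these genes was that of Myc, 0.0078. Of 41 measured immediate early genes, 26 were higher and 1 was lower (28 and 2 adjusted over the list alone), and the list as a whole was shifted upward (camera adjusted p = 7.89e-28, and adjusted p = 0.00725 with an estimated correlation).

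Acute phase genes, whose proteins the liver secretes in inflammation, had 7 of 26 members higher and 0 lower at 1 h (18 and 1 adjusted over the list alone). Their list test gave an adjusted p of 2.75e-10, and an adjusted p = 0.251 with an estimated correlation. The arrays of 1 h differed: Saa2 was at 12.40 in young replicate 1, at or below 8.11 in the other 2 young livers and at 13.05, 12.86 and 13.56 in old livers, and Lcn2 at 9.05, 5.09 and 4.92 in young livers and at 10.95, 9.81 and 12.36 in old livers. The inflammatory genes S100a8, a neutrophil calcium-binding protein, and Cxcl1, a neutrophil-attracting chemokine, rose by 2.41 ± 0.45 (adjusted p = 0.00107) and 2.09 ± 0.39 (adjusted p = 0.00117). The transcription factor genes Cebpd and Cebpb rose by 1.92 ± 0.29 and 1.12 ± 0.18. Among 23 genes of gluconeogenesis and the glucocorticoid or cAMP response, 5 were higher and 0 lower (7 and 1 adjusted over the list alone, camera adjusted p = 2.34e-05, and adjusted p = 0.0324 with an estimated correlation). Among these, G6pc, the last enzyme of glucose output, rose by 1.22 ± 0.21 (adjusted p = 0.000467).

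In all, 462 probe sets differed between PH and 0 h at 1 h, 244 higher and 218 lower. The PH arrays of this time had the low spike-in signal, and with that signal as a covariate 51 probe sets passed. Under that covariate Fos was 2.76 higher (adjusted p = 0.0839), Egr1 1.32 (adjusted p = 0.299), Myc 1.38 (adjusted p = 0.0694), Dusp1 0.85 (adjusted p = 0.424) and G6pc 0.83 (adjusted p = 0.213), while Hhex differed by -0.93 (adjusted p = 0.201). Nr4a1 kept its call with a smaller difference of 1.20 (limma adjusted p = 0.0228). The covariate works through the relation to the spike-in signal within groups, on which 1 array of another time weighs for Fos and Egr1. Old PH 0.5 h replicate 3, with a spike-in mean of 7.68, had Fos at 10.75 and Egr1 at 10.2. Replicates 1 and 2 had Fos at 4.48 and 4.40 and Egr1 at 6.95 and 6.62. Within the other groups, a spike-in gap of -2.31 predicted a Fos gap of 0.41 (95% interval -0.89 to 2.23). The cytoskeletal gene Actb fell by 1.94 (SE 0.36, adjusted p = 0.000987), and with the covariate its difference was -0.66 (adjusted p = 0.469). A separate beta-actin 3′ control probe set, in contrast, gave 12.7 in the PH arrays of 1 and 2 h and 12.3 at 0 h, a difference of 0.39 (exact permutation p = 0.0694, adjusted p = 0.208). The count of 462 was 307 without young 0 h replicate 1, 222 without old 0 h replicate 3, 286 without young PH replicate 1 and 289 without young PH replicate 2. It was 782 without old PH replicate 1 and 169 without old PH replicate 3. It was 224 when the compared groups alone were fitted and 925 with array weights. The larger side turned with array weights (439 higher and 486 lower) and with 2 arrays left out together (187 and 189).

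At 2 h after PH, the metallothioneins Mt2 and Mt1 were 4.95 ± 0.56 and 4.81 ± 0.60 log2 units above 0 h, and Igfbp1 was 4.10 ± 0.41 above it by 1 of its 2 probe sets (n = 6 and 6 arrays). Rcan1, an inhibitor of calcineurin, rose by 3.22 ± 0.18 and C9orf72 by 2.84 ± 0.16. Gadd45a rose by 2.40 ± 0.26, Btg2, an antiproliferative gene, by 2.15 ± 0.24 and Gadd45b by 1.60 ± 0.14. Fos was 2.90 ± 0.65 higher (1 of 2 probe sets), Atf3 3.50 ± 0.39 (2 of 3 probe sets) and Myc 1.55 ± 0.27. Socs3, the feedback inhibitor of IL-6 signalling, rose by 1.34 ± 0.22. The highest limma adjusted p among these genes was 0.00237, for Fos. Of the 41 immediate early genes, 25 were higher and 1 was lower (30 and 1 adjusted over the list alone, camera adjusted p = 1.47e-21, and adjusted p = 0.0143 with an estimated correlation).

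At 2 h, of 28 hepatocyte secreted and identity genes, 0 were higher and 11 lower (0 and 12 adjusted over the list alone). Their list test gave an adjusted p of 0.000148, and an adjusted p = 0.168 with an estimated correlation. Among liver transcription factor genes, Hhex fell by 1.99 (SE 0.22), Foxa2 by 1.33 (SE 0.12), Foxa1 by 1.27 (SE 0.26) and Cebpa by 0.63 (SE 0.14, adjusted p = 0.00224). Of 23 genes of gluconeogenesis and the glucocorticoid or cAMP response, 11 were higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 1.75e-08, and adjusted p = 0.00378 with an estimated correlation). G6pc rose by 1.46 ± 0.21 and Cebpb by 1.47 ± 0.18, and Lpin1, a phosphatidate phosphatase and transcriptional coregulator, by 1.81 ± 0.35. The transcriptional regulators Cited2 and Id2 fell by 1.57 and 1.49, each with a standard error of 0.23, and Sdc4, a cell-surface proteoglycan, by 1.92 (SE 0.33). In all, 713 probe sets were higher and 879 lower, and the larger side turned without old 0 h replicate 1 (718 and 706) or young PH replicate 3 (722 and 691). With the spike-in covariate 495 of the tested probe sets passed in limma. Fos was then 1.28 higher (adjusted p = 0.385) and Sdc4 differed by -0.97 (adjusted p = 0.0957). For Fos, the weight of old PH 0.5 h replicate 3 on the covariate, given for 1 h, applies here too. Actb fell by 2.47 (SE 0.36) and differed by -1.22 with that covariate (adjusted p = 0.0128), with the separate actin control probe set moving as given for 1 h. With array weights, 2925 probe sets passed.

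At 4 h after PH, Lcn2, the iron-scavenging acute phase protein lipocalin 2, rose by 5.79 ± 0.82 log2 units, Mt2 by 5.47 ± 0.56, Mt1 by 5.25 ± 0.60, the serum amyloid gene Saa2 by 4.44 ± 0.76 and Igfbp1 by 4.33 ± 0.41 (1 of 2 probe sets, n = 6 and 6 arrays). C9orf72 rose by 2.64 ± 0.16 and Mrap by 2.61 ± 0.16. Cxcl1 rose by 3.22 ± 0.39, the interleukin 1 receptor gene Il1r1 by 2.31 ± 0.38, Cebpd by 2.19 ± 0.29, Socs3 by 2.00 ± 0.22 and Cebpb by 1.86 ± 0.18. Of 24 IL-6 and STAT signalling genes, 15 were higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 2.17e-08, and adjusted p = 0.0555 with an estimated correlation). Of 36 NF-kB and chemokine genes, 18 were higher and 0 lower (22 and 0 adjusted over the list alone). Examples were Ccl2 at 1.66 ± 0.44, Cxcl2 at 1.42 ± 0.33 and Nfkbia at 1.15 ± 0.19, and the list test gave an adjusted p of 1.47e-07 and an adjusted p = 0.139 with an estimated correlation. Acute phase genes had 10 of 26 members higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 3.71e-08, and adjusted p = 0.371 with an estimated correlation). Of 19 neutrophil markers, 6 were higher and 0 lower (6 and 0 adjusted over the list alone), with S100a8 up by 1.63 ± 0.45 and S100a9 by 1.59 ± 0.36. That list gave an adjusted p of 0.014, and an adjusted p = 0.656 with an estimated correlation.

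At 4 h, of 37 ribosome biogenesis genes, 18 were higher and 0 lower (23 and 0 adjusted over the list alone). Among them the nucleolar genes Nop58, Rrs1 and Gnl3 rose by 1.44 ± 0.19, 0.96 ± 0.14 and 0.89 ± 0.18, and the list test gave an adjusted p of 3.82e-08 and an adjusted p = 0.139 with an estimated correlation. Of the 41 immediate early genes, 22 were higher and 2 lower (25 and 2 adjusted over the list alone, camera adjusted p = 4.85e-09, and adjusted p = 0.139 with an estimated correlation), with Klf6 up by 1.87 ± 0.20 and Myc by 1.19 ± 0.27. The cell cycle inhibitor gene Cdkn1a rose by 1.08 ± 0.08 (adjusted p = 3.44e-12). Cyclin D1 (Ccnd1) differed by 0.15 ± 0.13 (adjusted p = 0.443) and hepatocyte growth factor (Hgf) by 0.10 ± 0.07 (adjusted p = 0.303), neither past the threshold. Hgf ran from 0.04 without old PH replicate 1 to 0.16 without old PH replicate 3. Of 37 cell cycle genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.177), among them Rrm2 at 0.50 ± 0.10 and Mki67 at 0.36 ± 0.09 (1 of 2 probe sets). Of 20 hypoxia and oxidative stress genes, 7 were higher and 2 lower (8 and 2 adjusted over the list alone), with Hmox1 up by 1.65 ± 0.21 and Txnrd1 by 1.08 ± 0.13. Their list test gave an adjusted p of 0.014, and an adjusted p = 0.139 with an estimated correlation.

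Also at 4 h, of 15 genes of bile acid synthesis and transport, 1 was higher and 9 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.0032, and adjusted p = 0.385 with an estimated correlation). Hsd3b7, an enzyme of bile acid synthesis, fell by 0.81 (SE 0.11), and Nr0b2, the bile acid-induced repressor SHP, by 0.74 (SE 0.18). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.08 (SE 0.31, adjusted p = 0.0111), a call that was lost without old 0 h replicate 1 (-0.85, adjusted p = 0.0524). Of 28 hepatocyte secreted and identity genes, 1 was higher and 11 lower (1 and 11 adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.448 with an estimated correlation). Hhex fell by 2.58 (SE 0.22), Foxa1 by 1.97 (SE 0.26), Foxa2 by 0.91 (SE 0.12) and Cebpa by 0.85 (SE 0.14). The growth factor receptor gene Erbb3 fell by 2.02 (SE 0.22) and the tight junction genes Cldn1 and Cldn3 by 1.94 and 1.78. In all, 1431 probe sets were higher and 1492 lower at 4 h, and the larger side turned without young 0 h replicate 1 (1305 and 1279) or old 0 h replicate 1 (1349 and 1252).

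**Figure D2:**
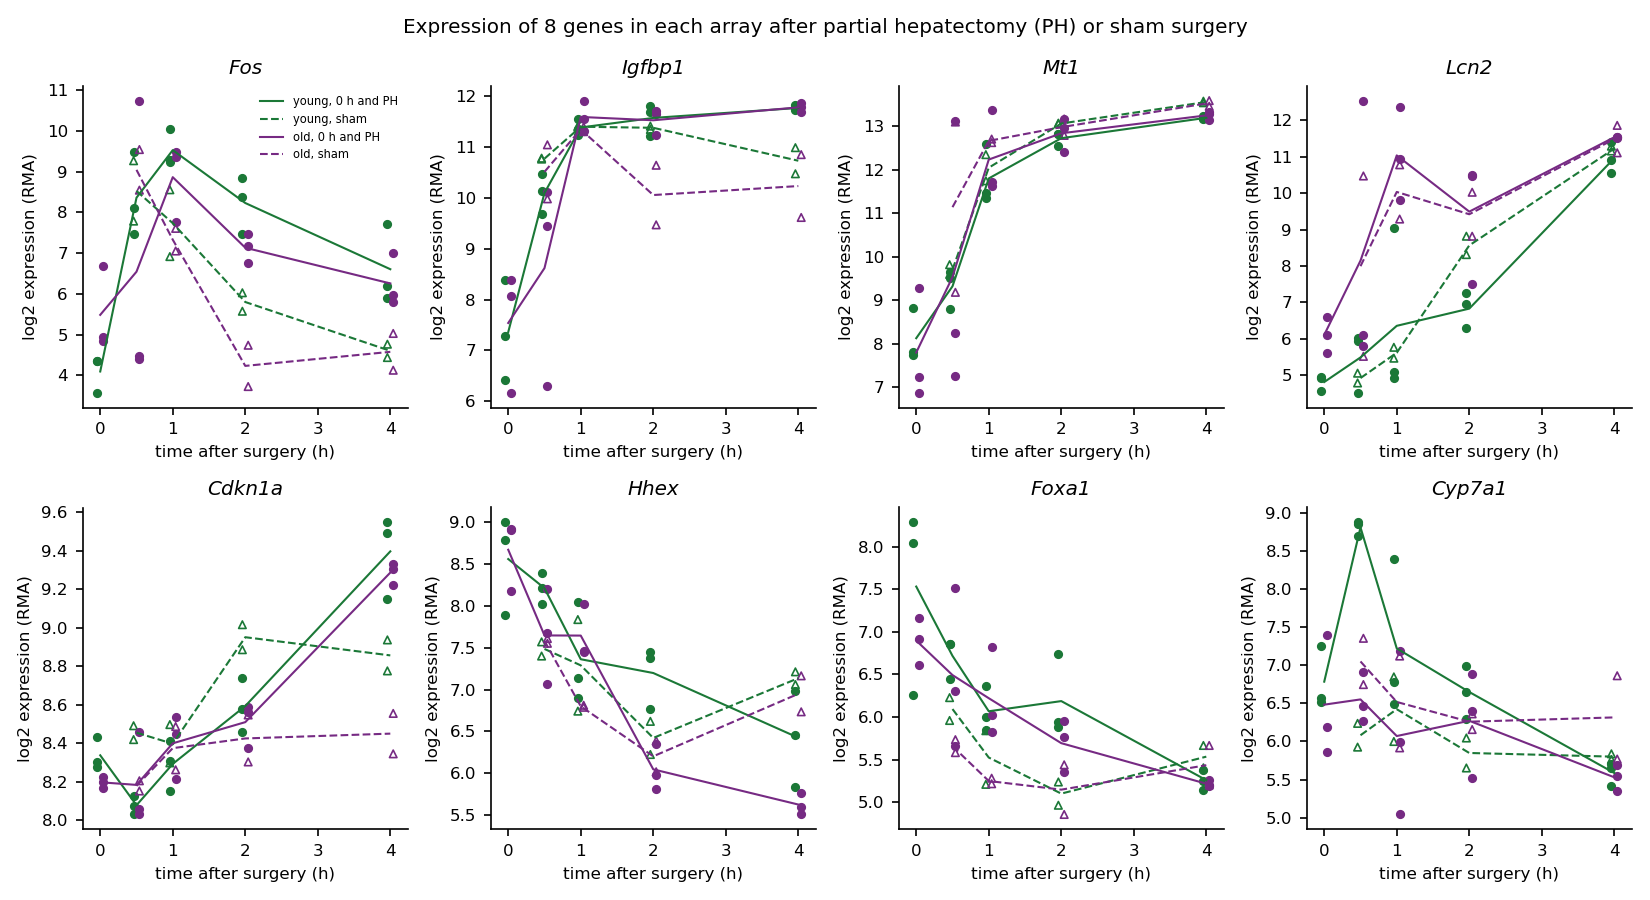
Log2 expression of 8 genes (Fos, Igfbp1, Mt1, Lcn2, Cdkn1a, Hhex, Foxa1 and Cyp7a1) against hours after surgery, with a point per array, lines through group means, solid for 0 h and PH, dashed for sham, green for young and purple for old. At 4 h after PH, Lcn2 was 5.79 and Cdkn1a 1.08 above 0 h in the mean of both ages, while Hhex had fallen by 2.58.

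Each age was also compared with its own 0 h arrays. At 4 h in young livers Lcn2 was 6.15 ± 1.16 log2 units above 0 h (1 of 2 probe sets), Cdkn1a was 1.06 ± 0.11 above it, and Foxa1 and Hhex fell by 2.27 (SE 0.36) and 2.13 (SE 0.31), with 3 arrays per group. In old livers Lcn2 was 5.43 ± 1.16 and Cdkn1a 1.09 ± 0.11 above 0 h, while Foxa1 fell by 1.68 (SE 0.36) and Hhex fell by 3.04 (SE 0.31). At 4 h, 407 probe sets were higher and 545 lower in young livers, and 989 and 861 in old livers. In both ages 295 probe sets were higher and 395 lower. The larger side turned in young livers with median centring (465 and 461) and without PH replicate 1 (286 and 262). It turned in old livers with median centring (844 and 990), the dimmest probe sets left out (769 and 818), 1 probe set per gene (667 and 695), cross-hybridisation suffixes left out (719 and 739) and without 0 h replicate 3 (707 and 765). Of the 407 higher in young livers, 401 (98.5%) had the same sign in old livers. At 2 h, 144 were higher in both ages and 85 lower, and at 1 h, 38 were higher and 2 lower.

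The time course began with few calls in each age. At 0.5 h in young livers, 5 probe sets passed, and the genes were named because the count was small. Per2 and Noct, genes with a daily rhythm in liver, rose by 1.49 ± 0.21 and 1.45 ± 0.21 (adjusted p = 0.000276 for both, Noct by 1 of 3 probe sets), and passed in all 6 fits without 1 array. Thrsp, a lipogenic gene, was 2.14 ± 0.39 higher (adjusted p = 0.0126). Its call was lost without young 0 h replicate 1 (1.88, adjusted p = 0.249), replicate 2 (1.84, adjusted p = 0.114), or PH replicate 1 (2.11, adjusted p = 0.0813) or 3 (2.03, adjusted p = 0.121). Zbtb16, a transcriptional repressor, fell by 2.57 (SE 0.47, adjusted p = 0.013, 1 of 2 probe sets). Its call was lost without 0 h replicate 1 (-2.50, adjusted p = 0.199), 0 h replicate 2 (-2.58, adjusted p = 0.0636), PH replicate 2 (-2.05, adjusted p = 0.174) or PH replicate 3 (-2.36, adjusted p = 0.143), and when the compared groups alone were fitted (adjusted p = 0.065). For Usp2, a rhythmic deubiquitinase gene, 1 probe set was 1.12 ± 0.19 higher (adjusted p = 0.0078). It lost its call without 0 h replicate 1 or 2 or PH replicate 1, with an adjusted p of up to 0.199, and the brighter Usp2 probe set did not pass (1.09, adjusted p = 0.0988). The brighter one passed without 0 h replicate 3 (1.55, adjusted p = 0.000436), with 2 arrays left out together (1.55, adjusted p = 0.000614) and with array weights (1.49, adjusted p = 4.12e-06), and it was at 8.32 in 0 h replicate 3 and at 6.85 and 7.01 in replicates 1 and 2. The count of 5 was 2 without 0 h replicate 1, 14 without 0 h replicate 3 and 3 without PH replicate 3. With array weights it was 638, of which 277 were higher and 361 lower.

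In old livers at 0.5 h, 0 probe sets passed in limma, while 1112 had an unadjusted p under 0.05 where 621.1 would be expected by chance. Igfbp1 was 1.08 ± 0.57 higher (adjusted p = 0.594), Jun 1.05 ± 0.22 (adjusted p = 0.122) and Fos 1.06 ± 0.92 (adjusted p = 0.775). Fos was at 10.75 in old PH replicate 3 and at 4.48 and 4.40 in replicates 1 and 2, and without replicate 3 its difference was -1.04. Without old PH replicate 2, Jun was 1.33 higher (adjusted p = 0.00584) and Igfbp1 was 2.24 higher (adjusted p = 0.0474), while without replicate 3 Jun was 0.68 higher (adjusted p = 0.194) and Igfbp1 0.33 (adjusted p = 0.919). Igfbp1 was 0.39 higher without old 0 h replicate 3 and 0.67 without PH replicate 1. Fos was 0.14 higher with the spike-in covariate (adjusted p = 0.986). Replicate 2 had the highest 3′ to 5′ difference of the actin control of all 46 arrays, 2.06, with 1.39 the next highest, and a Gapdh difference of 0.679. The count of 0 became 3 without old 0 h replicate 1, 2 without old 0 h replicate 3, 9 without PH replicate 2 and 23 without PH replicate 3.

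At 1 h, 56 probe sets were higher and 15 lower in young livers, and 150 higher and 51 lower in old livers. The total of 71 in young livers was 44 without young 0 h replicate 1, 40 without young 0 h replicate 2 and 33 without young PH replicate 2. With array weights the direction turned, with 259 higher and 614 lower. The total of 201 in old livers was 72 without old 0 h replicate 2, 56 without old 0 h replicate 3, 568 without PH replicate 1, 416 without PH replicate 2 and 25 without PH replicate 3. At 2 h, 218 were higher and 278 lower in young livers and 377 and 273 in old livers. The young total of 496 was 249 without 0 h replicate 1, 290 without 0 h replicate 2, 316 without PH replicate 1 and 292 without PH replicate 2. Its larger side turned with median centring (268 higher and 190 lower), the compared groups alone (244 and 208) and without 0 h replicate 1 (149 and 100), 0 h replicate 2 (148 and 142), PH replicate 2 (154 and 138) or PH replicate 3 (230 and 162). The old total of 650 was 323 without 0 h replicate 2, 322 without 0 h replicate 3, 315 without PH replicate 1 and 353 without PH replicate 3. At 4 h, the young total of 952 was 603 without 0 h replicate 1, 602 without 0 h replicate 2 and 548 without PH replicate 1. The old total of 1850 was 1083 without 0 h replicate 2 and 1073 without PH replicate 3.

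**Figure D3:**
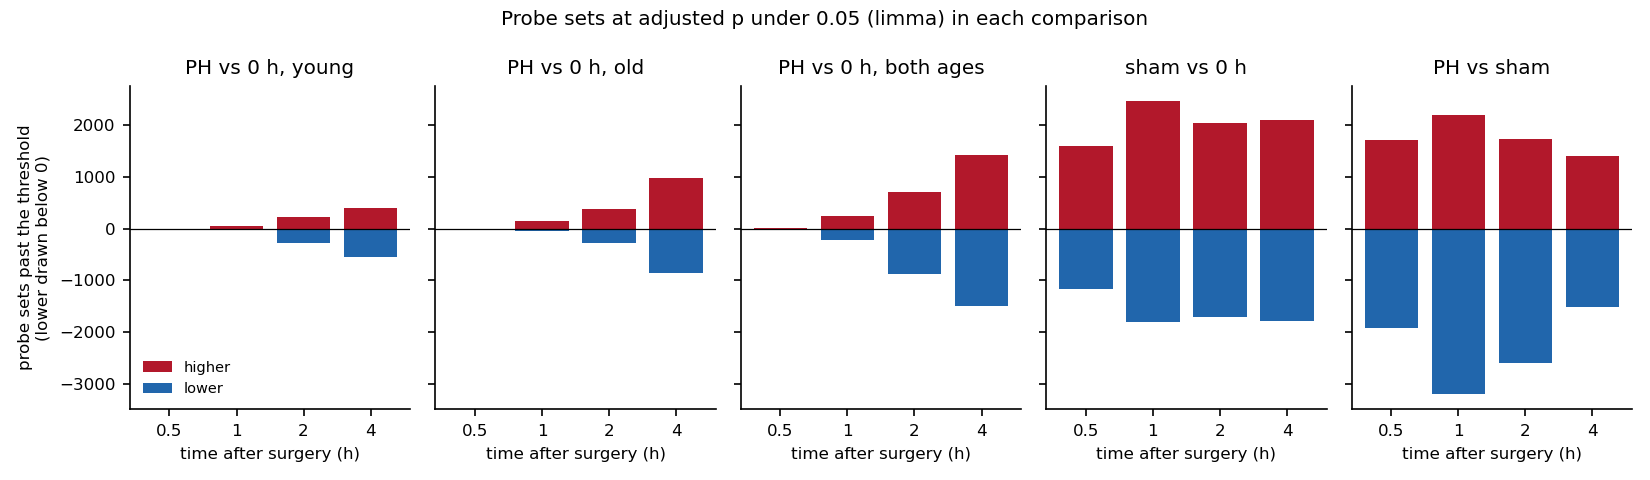
Probe sets past an adjusted p of 0.05, higher and lower, for each comparison by hours after surgery. PH against 0 h over both ages rose from 11 probe sets at 0.5 h to 2923 at 4 h, while PH against sham and sham against 0 h had 2769 or more at every time.

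The sham arrays, which stood apart on the first principal component, were compared with 0 h (n = 4 sham and 6 control arrays per time). At 0.5 h, Fos was 4.00 ± 0.73 log2 units above 0 h (1 of 2 probe sets), Igfbp1 was 3.19 ± 0.45 above it and Egr1 2.33 ± 0.45 (1 of 2 probe sets). At 1 h, Mt1 rose by 4.39 ± 0.67, Mt2 by 4.36 ± 0.62, Igfbp1 by 3.93 ± 0.45, Fos by 2.75 ± 0.73 (1 of 2 probe sets) and Atf3 by 2.24 ± 0.43. Of 41 immediate early genes at 1 h, 21 were higher and 3 lower (25 and 3 adjusted over the list alone, camera adjusted p = 0.00115, and adjusted p = 0.763 with an estimated correlation). At 4 h, Lcn2 was 5.90 ± 0.92 higher (1 of 2 probe sets), Mt1 5.57 ± 0.67, Saa2 4.82 ± 0.85, Il1r1 2.48 ± 0.42 and Cxcl1 2.46 ± 0.44. Socs3 rose by 1.09 ± 0.24, while Myc differed by -0.37 ± 0.30 (adjusted p = 0.363), by -0.17 without young 0 h replicate 1 and by -0.61 without young 0 h replicate 3. Of 26 acute phase genes at 4 h, 15 were higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 8.63e-07, and adjusted p = 0.637 with an estimated correlation), against 3 higher and 1 lower at 0.5 h and 4 and 0 at 1 h. Foxa1 fell by 1.73 (SE 0.29), Cited2 by 1.85 (SE 0.25) and Cldn1 by 2.18 (SE 0.29).

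The counts of sham against 0 h were large from the start, with 1601 probe sets higher and 1168 lower at 0.5 h, 2478 and 1808 at 1 h, 2040 and 1714 at 2 h, and 2109 and 1778 at 4 h. At 0.5 h the potassium channel gene Kcnj9 was 1.91 ± 0.24 higher (1 of 2 probe sets), and Phlda1 fell by 2.93 (SE 0.39). Sham surgery and the sham array set could not be separated in any comparison with 0 h or PH arrays. The 0.5 h total of 2769 was 1369 without young sham replicate 1, 1787 without old sham replicate 2 and 4358 with array weights. The 1 h total of 4286 was 2598 without old sham replicate 2. The 2 h total of 3754 was 2322 without young sham replicate 2 and 1772 without old sham replicate 2 (882 higher and 890 lower), and the 4 h total of 3887 was 5905 with array weights. At 4 h the larger side turned with the dimmest probe sets left out (1651 and 1656).

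Changes among the sham arrays themselves do not involve the levels of other arrays (n = 4 per time). Their standard errors and p-values still use the spread within all 18 groups. Between 0.5 and 4 h, Lcn2 rose by 4.90 ± 1.01, Fkbp5, a glucocorticoid-induced gene, by 2.38 ± 0.36 and Il1r1 by 2.33 ± 0.46, while Fos fell by 4.20 (SE 0.79), Egr1 by 2.68 (SE 0.49) and Dusp6 by 1.69 (SE 0.35), the last 3 by 1 of 2 probe sets each. The gluconeogenic gene G6pc fell by 2.01 (SE 0.26) and Cldn1 by 1.67 (SE 0.32). Lcn2 was at 10.47 in old sham 0.5 h replicate 1 and at 5.05, 4.78 and 5.51 in the other 3 arrays of that time. Its change ran from 3.66 to 6.14 in the fits without 1 array, and its call was lost without old sham 0.5 h replicate 2 (3.66, adjusted p = 0.0852). Of 16 cholesterol synthesis genes, 0 were higher and 5 lower (0 and 10 adjusted over the list alone, camera adjusted p = 6.89e-09, and adjusted p = 0.197 with an estimated correlation), with Fdft1, squalene synthase, falling by 0.93 (SE 0.18). Of 16 lipogenesis genes, 1 was higher and 6 lower (1 and 8 adjusted over the list alone, camera adjusted p = 3.35e-07, and adjusted p = 0.0622 with an estimated correlation), with Fasn, fatty acid synthase, falling by 1.06 (SE 0.18). Of 26 acute phase genes, 6 were higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 1.1e-15, and adjusted p = 0.16 with an estimated correlation). Of 41 immediate early genes, 0 were higher and 5 lower (1 and 9 adjusted over the list alone, camera adjusted p = 0.0457, and adjusted p = 0.961 with an estimated correlation).

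By 4 h, 149 probe sets were higher and 137 lower than at 0.5 h in the sham arrays, and by 2 h, 17 and 4. The 4 h total of 286 was 117, 145 and 120 without young 0.5 h replicate 1, young 0.5 h replicate 2 and old 0.5 h replicate 2. It was 180, 113, 169 and 98 without young 4 h replicates 1 and 2 and old 4 h replicates 1 and 2. The larger side turned without young 0.5 h replicate 1 (53 higher and 64 lower), old 0.5 h replicate 2 (58 and 62), young 4 h replicate 1 (78 and 102) or old 4 h replicate 2 (46 and 52). It also turned with array weights (348 and 432), the dimmest probe sets left out (156 and 164), 1 probe set per gene (122 and 126) and cross-hybridisation suffixes left out (127 and 130). The 2 h total of 21 was 8, 7 and 9 without young 0.5 h replicate 1, young 0.5 h replicate 2 and old 0.5 h replicate 2. It was 6, 9, 5 and 10 without young 2 h replicates 1 and 2 and old 2 h replicates 1 and 2. At 1 h, the 3 probe sets that passed were named because the count was small. Apob, the apolipoprotein of secreted lipoproteins, rose by 1.34 ± 0.17 (adjusted p = 9.33e-05) and passed in all 8 fits without 1 array. Rcan1 rose by 1.40 ± 0.22 (adjusted p = 0.00289), a call lost without young 0.5 h replicate 2 (1.25, adjusted p = 0.0684), young 1 h replicate 1 (1.32, adjusted p = 0.0613) or old 1 h replicate 2 (1.26, adjusted p = 0.0636), and with the compared groups alone (adjusted p = 0.142). The gene 1700017B05Rik rose by 0.74 ± 0.13 (adjusted p = 0.00525), a call lost without young 0.5 h replicate 1 (0.71, adjusted p = 0.0817), old 0.5 h replicate 2 (0.67, adjusted p = 0.0893) or young 1 h replicate 1 (0.65, adjusted p = 0.187), and with the compared groups alone (adjusted p = 0.28). The count of 3 was 1 without young 1 h replicate 1 and 23 without old 1 h replicate 1.

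PH and sham livers were compared at the same time to set liver removal against surgery alone (n = 6 and 4 arrays). At 2 h, Fos was 2.67 ± 0.73 higher after PH (1 of 2 probe sets), Rcan1 2.07 ± 0.20, the ERK phosphatase gene Dusp6 2.03 ± 0.32 and Myc 1.41 ± 0.30. Atf3 was 2.24 ± 0.43 higher by 2 of its 3 probe sets, with the other passing in the opposite direction. Of 41 immediate early genes at 2 h, 23 were higher and 2 lower (25 and 3 adjusted over the list alone, camera adjusted p = 2.37e-07, and adjusted p = 0.708 with an estimated correlation). With the spike-in covariate Fos at 2 h was 1.43 higher (limma adjusted p = 0.129), with old PH 0.5 h replicate 3 weighing on that covariate as given above. At 4 h, the melanocortin receptor accessory gene Mrap was 1.93 ± 0.18 higher after PH, Dusp6 1.84 ± 0.32, C9orf72 1.78 ± 0.18, Myc 1.55 ± 0.30, Cebpb 1.26 ± 0.21, Cdkn1a 0.69 ± 0.09 and Hgf 0.31 ± 0.08. Against 0 h, Hgf had not passed at 4 h, as given above, so its gap to sham also holds lower values in the sham arrays, which stood apart as a set. Saa2 differed by -0.38 ± 0.85 (limma adjusted p = 0.781).

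Immediate early genes at 4 h had 18 of 41 members higher after PH than after sham surgery and 1 lower (24 and 1 adjusted over the list alone, camera adjusted p = 2.07e-07, and adjusted p = 0.49 with an estimated correlation). Of 16 lipogenesis genes, 5 were higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.00796, and adjusted p = 0.49 with an estimated correlation), with the fatty acid elongase gene Elovl6 higher by 0.97 ± 0.17 and Fasn by 0.93 ± 0.16. Among 15 exocrine pancreas markers, which would report pancreatic tissue in a sample, 0 were higher and 5 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.182). At 0.5 h, Phlda1 was 1.80 ± 0.39 and Apob 1.67 ± 0.16 higher after PH, while Kcnj9 differed by -2.07 ± 0.24 (1 of 2 probe sets). The totals were 1718 higher and 1913 lower at 0.5 h, 2195 and 3207 at 1 h, 1727 and 2602 at 2 h, and 1403 and 1518 at 4 h. They include what sets the sham arrays apart. The 0.5 h total of 3631 was 2203 without young sham replicate 1, and its larger side turned without old PH replicate 1 (1763 and 1761). The 2 h total of 4329 was 2811 without young sham replicate 2 and 2175 without old sham replicate 2. The 4 h total of 2921 was 1918 and 1937 without old sham replicates 1 and 2. Its larger side turned with median centring (1514 and 1449), the compared groups alone (1432 and 1360) and without young PH replicate 3 (1198 and 1158).

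A constant offset between the sham arrays and the other arrays cancels in the change of the PH to sham difference since 0.5 h (n = 6 and 4 arrays per time). It is the PH change minus the sham change, so it also moves when the sham arrays alone move. As given above, the sham arrays themselves fell for Dusp6 and Fasn by 4 h and rose for Apob by 1 h. By 4 h this difference had risen by 2.20 ± 0.45 for Dusp6 (1 of 2 probe sets), 1.96 ± 0.25 for Mrap, 1.70 ± 0.26 for C9orf72, 1.13 ± 0.23 for Fasn and 0.87 ± 0.12 for Cdkn1a. It fell by 1.21 (SE 0.19) for Rreb1, a zinc finger transcription factor. For Myc it was 1.04 ± 0.42 (adjusted p = 0.227). By 2 h it had risen by 1.86 ± 0.26 for C9orf72, 1.58 ± 0.29 for Rcan1 and 1.52 ± 0.25 for the small MAF factor gene Maff, and it fell by 1.56 (SE 0.23) for Apob. Of 41 immediate early genes, 4 had risen and 1 had fallen by 2 h (18 and 2 adjusted over the list alone, camera adjusted p = 6.03e-15, and adjusted p = 0.145 with an estimated correlation). By 4 h, 4 had risen and 0 had fallen (12 and 1 adjusted over the list alone, camera adjusted p = 4.62e-09, and adjusted p = 0.47 with an estimated correlation). With the spike-in covariate, Rcan1 at 2 h gave 1.33 (adjusted p = 0.103) and Maff 1.27 (adjusted p = 0.0574).

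In this comparison the difference rose at 36 probe sets and fell at 28 by 2 h, and rose at 80 and fell at 116 by 4 h. At 1 h 2 passed, named because the count was small. For Cpeb2, a regulator of translation, the difference rose by 1.57 ± 0.30 (adjusted p = 0.0467). For Apob, which rose in the sham arrays alone over this interval, it fell by 1.50 (SE 0.23, adjusted p = 0.00162). Apob passed in all 20 fits without 1 array and gave -1.28 with the spike-in covariate (adjusted p = 0.0918). Cpeb2 passed in 4 of the 20, those without young PH 0.5 h replicate 1, old PH 0.5 h replicate 3, young PH 1 h replicate 1 or old sham 0.5 h replicate 2, and ranged from 1.41 to 1.73 with an adjusted p of up to 0.416. Its call was also lost with trend and robust settings (adjusted p = 0.108), the compared groups alone (0.854), the replicate block (0.0683), array weights (0.571) and the spike-in covariate (0.998). The count of 2 was 6 without old PH 0.5 h replicate 3, 5 without young PH 1 h replicate 1, and 1 in 15 of the other fits without 1 array. The 2 h total of 64 was 42 and 161 without old PH 0.5 h replicates 2 and 3, 42 without young PH 2 h replicate 1 or 2 and 107 without replicate 3. It was 15 without young sham 0.5 h replicate 1, 33 without old sham 0.5 h replicate 1 (16 rising and 17 falling) and 15 without young sham 2 h replicate 2. With the spike-in covariate it was 7. Without old sham 2 h replicate 2, 21 rose and 23 fell. The 4 h total of 196 was 123 without young PH 0.5 h replicate 3, 128 without young PH 4 h replicate 1 and 124 without old PH 4 h replicate 3. It was 75 without young sham 0.5 h replicate 1, 112 without old sham 0.5 h replicate 2, 73 without young sham 4 h replicate 2, and 58 and 129 without old sham 4 h replicates 1 and 2.

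**Figure D4:**
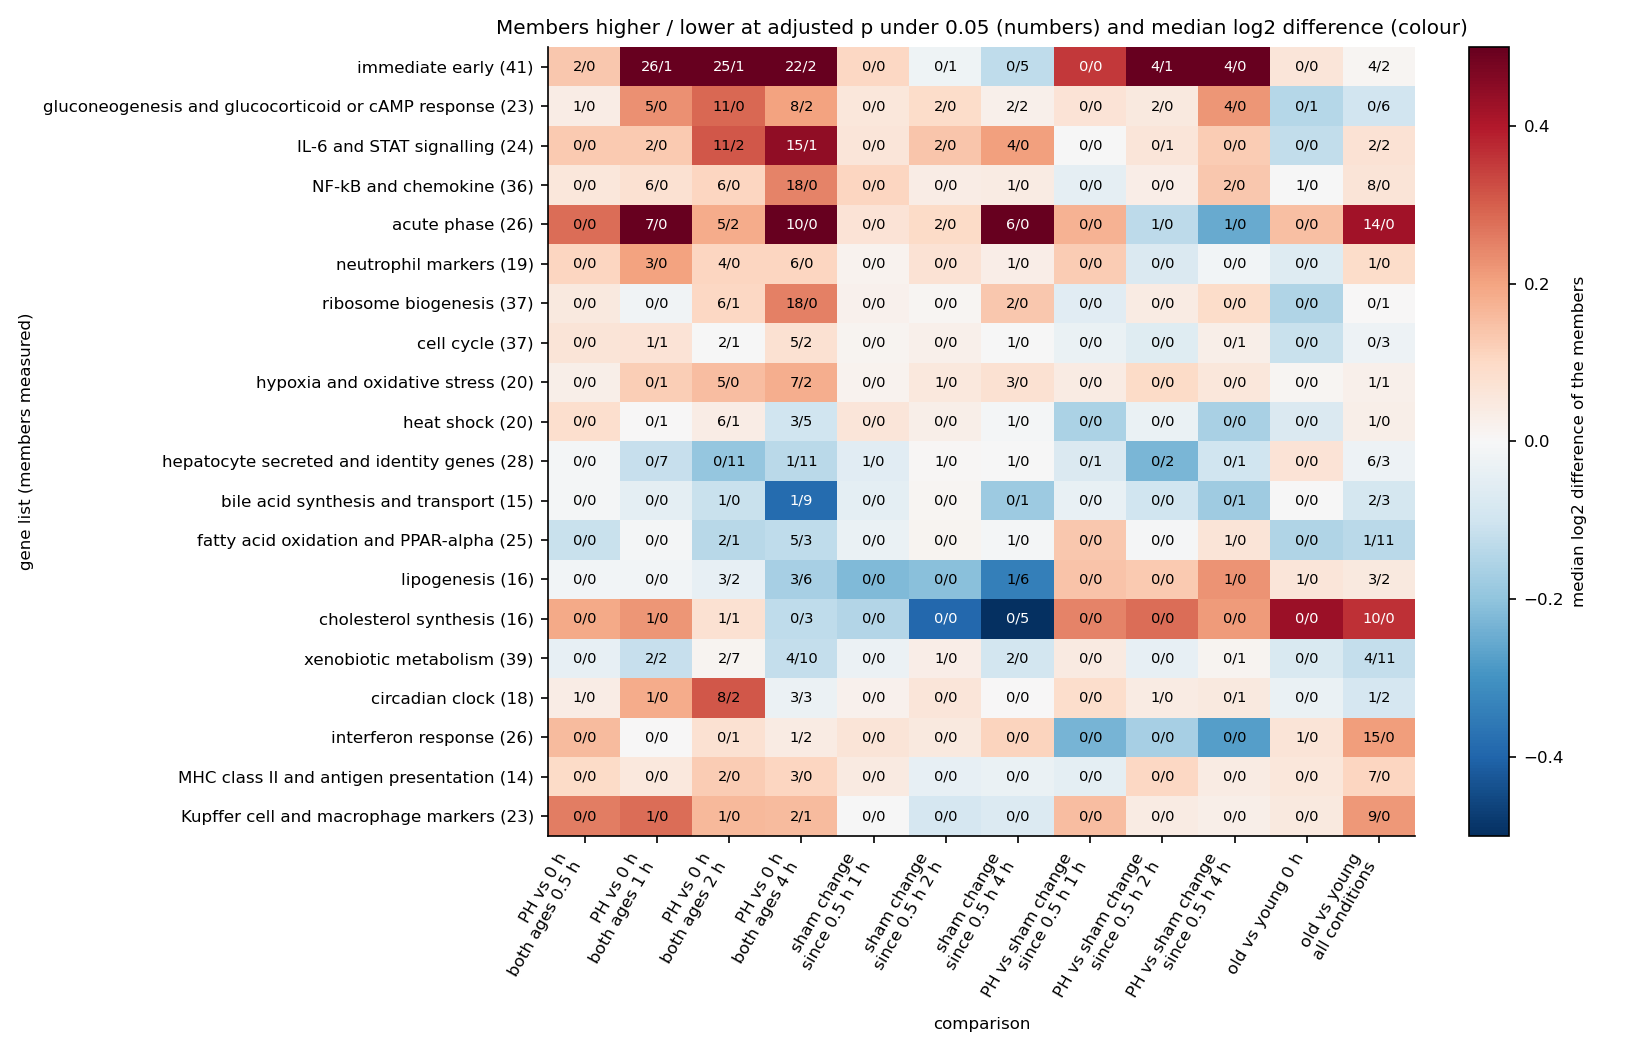
Median log2 difference of the measured members of 20 gene lists (vertical) in 12 comparisons (horizontal), with the numbers of members higher and lower written in each cell. Immediate early genes had 26 of 41 members higher and 1 lower at 1 h after PH against 0 h. In the change of the PH to sham difference since 0.5 h, 4 were higher and 1 lower by 2 h.

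Old and young livers were compared over the 9 conditions (n = 23 and 23 arrays). Lcn2 was 2.28 ± 0.43 log2 units higher in old livers (1 of 2 probe sets), the acute phase gene Orm2 1.79 ± 0.37, Cxcl1 1.27 ± 0.20 and Socs3 0.46 ± 0.11. The gap in group means was not the same at each time, although no test of age in the PH response called Lcn2, Orm2 or Cxcl1. The old and young means of Lcn2 were 11.04 and 6.35 at 1 h after PH but 11.54 and 10.96 at 4 h after PH and 11.49 and 11.23 at 4 h after sham surgery, and those of Orm2 12.81 and 9.38 at 1 h and 10.57 and 9.97 at 4 h after PH. Those of Cxcl1 were 11.42 and 9.47 at 1 h and 11.73 and 11.42 at 4 h after PH. Single old 0.5 h arrays had Lcn2 at 12.55 (PH replicate 1) and 10.47 (sham replicate 1). The interferon-induced genes Ly6e and Ifi27 were 1.23 ± 0.08 (1 of 2 probe sets) and 1.18 ± 0.07 higher, and the immunoproteasome gene Psmb8 0.76 ± 0.09. Noct, a gene with a daily rhythm, was 1.39 ± 0.08 higher (adjusted p = 3.4e-15). The highest adjusted p among these genes was that of Socs3, 0.00793. Of 26 interferon response genes, 15 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 2.45e-19, and adjusted p = 0.0632 with an estimated correlation). Of 26 acute phase genes, 14 were higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 6.76e-10, and adjusted p = 0.251 with an estimated correlation). The old and young mice came from different suppliers, so these differences also follow supplier.

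Cell type markers were compared over the same arrays. Of 23 Kupffer cell and macrophage markers, 9 were higher and 0 lower (13 and 0 adjusted over the list alone), with the lysozyme gene Lyz2 at 0.95 ± 0.15, Mpeg1 at 0.86 ± 0.09 (each by 1 of 2 probe sets) and the protease gene Ctss at 0.81 ± 0.13. That list gave an adjusted p of 4.24e-09, and an adjusted p = 0.251 with an estimated correlation. Of 14 MHC class II and antigen presentation genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 5.12e-06, and adjusted p = 0.204 with an estimated correlation), with the invariant chain gene Cd74 at 0.74 ± 0.12. Of 13 B and plasma cell markers, 3 were higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.105), with Jchain at 0.93 ± 0.22 and the heavy chain gene Ighm at 1.44 ± 0.23, the latter by 3 of its 16 probe sets. Single old arrays stood far above the others: Ighm was at 12.94 in old PH 4 h replicate 3, against 8.68 and 8.66 in replicates 1 and 2, and at 11.80 in old PH 2 h replicate 3, and Jchain was at 8.77 and 7.78 in the same 2 arrays. Both genes passed in each of the 46 fits without 1 array, Ighm at 1.28 to 1.52 and Jchain at 0.79 to 1.00.

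Among metabolic genes, of 16 cholesterol synthesis genes, 10 were higher and 0 lower in old livers (13 and 0 adjusted over the list alone, camera adjusted p = 1.58e-10, and adjusted p = 0.16 with an estimated correlation), with Sqle at 0.70 ± 0.12, Hmgcs1 at 0.67 ± 0.13 and Idi1 at 0.56 ± 0.12. Of 25 genes of fatty acid oxidation and PPAR-alpha, 1 was higher and 11 lower (2 and 12 adjusted over the list alone, camera adjusted p = 6.38e-05, and adjusted p = 0.343 with an estimated correlation). The fatty acid hydroxylase gene Cyp4a10 differed by -1.46 ± 0.26 (adjusted p = 0.000242), and by -0.93 (adjusted p = 0.0451) without the sham arrays, and Acot1 differed by -0.80 ± 0.09. Of 39 xenobiotic metabolism genes, 4 were higher and 11 lower (5 and 14 adjusted over the list alone, camera adjusted p = 0.000341, and adjusted p = 0.297 with an estimated correlation), with the cytochrome P450 genes Cyp2b10 at -0.61 ± 0.11 and Cyp1a2 at -0.43 ± 0.07. Of 23 genes of gluconeogenesis and the glucocorticoid or cAMP response, 0 were higher and 6 lower (0 and 7 adjusted over the list alone, camera adjusted p = 0.000218, and adjusted p = 0.1 with an estimated correlation), Lpin1 among them at -0.93 ± 0.18. The bile acid 12-alpha-hydroxylase gene Cyp8b1 differed by -0.73 ± 0.17 (adjusted p = 0.00438). In all, 624 probe sets were higher and 485 lower in old livers.

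At 0 h alone (n = 3 and 3 arrays), 16 probe sets were higher and 2 lower in old livers. Noct was 2.11 ± 0.21 higher (adjusted p = 8.85e-08, 2 of 3 probe sets) and passed in all 6 fits without 1 array. Cxcl1 was 2.55 ± 0.55 higher (adjusted p = 0.0397) and Ifi27 1.06 ± 0.19 (adjusted p = 0.00889). Cxcl1 lost its call without young replicate 2 (2.57, adjusted p = 0.114), young replicate 3 (2.21, adjusted p = 0.374), old replicate 1 (2.18, adjusted p = 0.31) or old replicate 3 (2.25, adjusted p = 0.29). Its call was also lost with trend and robust settings (adjusted p = 0.107), the compared groups alone (0.194), 1 probe set per gene (0.0777), cross-hybridisation suffixes left out (0.0652), the spike-in covariate (0.0986) and 2 arrays left out together (0.401). Ifi27 lost its call without young replicate 3 (0.99, adjusted p = 0.0785), old replicate 1 (1.01, adjusted p = 0.0713) or old replicate 3 (0.98, adjusted p = 0.0524), and with 2 arrays left out together (adjusted p = 0.0689). The count of 18 was 7 and 9 without young replicates 2 and 3, and 6 and 8 without old replicates 1 and 2. With array weights the direction turned, with 116 higher and 507 lower.

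**Figure D5:**
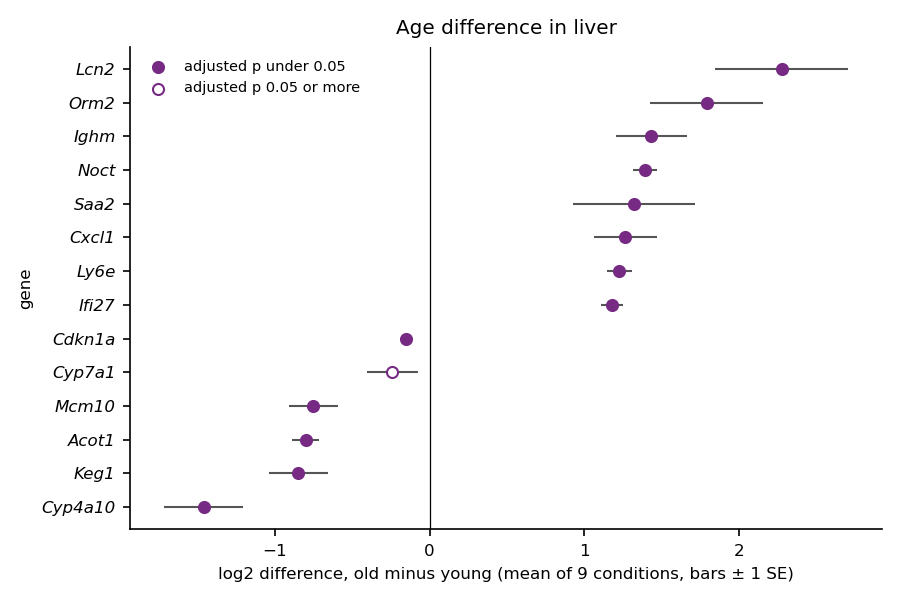
Mean log2 difference between old and young livers over the 9 conditions for 14 genes, with bars of 1 standard error and open points for genes not past the threshold. Lcn2 was highest at 2.28 and Cyp4a10 lowest at -1.46, and Cyp7a1 did not pass.

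Whether the PH response differed with age was tested directly. Against 0 h, the F test over the 4 times called 0 probe sets in limma, with 921 at an unadjusted p under 0.05 where 621.1 would be expected by chance. On simulated data with the same shift at all 4 times, this F test recovered 35.8% of changes of 0.5 log2 units and 83.6% of changes of 1 log2 unit. The count of 0 therefore leaves small age differences open. Differences at a single time were not simulated, so larger ones of that kind stay open too. Against sham, it called 1, a probe set of Usp2 (adjusted p = 0.00231), which passed in each of the 40 fits without 1 array, while the brighter Usp2 probe set did not pass (adjusted p = 0.0593). Separate tests by time against 0 h were added after the data had been seen, and were not repeated with arrays left out. In them 1 probe set passed at 0.5 h, of the splicing factor gene Srsf5. Its PH change was 1.52 lower in old livers (-1.52 ± 0.23, adjusted p = 0.00136). Its mean went from 8.06 to 8.84 in young livers and from 8.67 to 7.93 in old livers, and both genes were named because the counts were small. At 1, 2 and 4 h limma called 0, with 607, 652 and 563 at an unadjusted p under 0.05.

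Leaving out 1 array moved the count of 0 against 0 h to between 1 and 4 in 13 fits and to 11 without young PH 1 h replicate 1. Those with 1 were old 0 h replicate 3, young PH 0.5 h replicate 1, old PH 1 h replicates 2 and 3 and old PH 2 h replicate 1. Those with 2 were old 0 h replicate 1, old PH 0.5 h replicate 3, young PH 2 h replicates 2 and 3, old PH 2 h replicate 2 and old PH 4 h replicate 1. Without young PH 4 h replicate 1 it was 3, and without young 0 h replicate 3 it was 4. Against sham, the count of 1, the Usp2 probe set, was 120 without old sham 1 h replicate 1 and 12 without young PH 1 h replicate 1. It was 3 without old PH 2 h replicate 3 or old sham 0.5 h replicate 2. It was 2 without young PH 0.5 h replicate 3, old PH 2 h replicate 2, old PH 4 h replicate 1, young sham 4 h replicate 2 or old sham 4 h replicate 2.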

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

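The tests on the sham arrays and on the clock genes, the spike-in test of Fos alone, the array resampling and the comparisons of changes since 0.5 h, were chosen after the results had been seen. So were the age tests at single times. The rule that leaves degradation open was set after its count was known, and the array-level clock test replaced 2 permutation tests over genes, with p = 0.0455 for all genes and 0.0476 without the genes called, because they treated co-regulated genes as independent.

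The sham arrays differed from the 0 h arrays at 2769 probe sets already at 0.5 h, among them Kcnj9 and Phlda1. Shared anaesthesia and opening of the abdomen would have moved these probe sets in PH livers too, but the median ratio of the PH to the sham change was -0.0289 (95% interval -0.204 to 0.115 from all resamples of arrays within groups), with 45.3% of the 2769 of the same sign. RNA degradation stays open. With the 3′ to 5′ difference of the control probe sets as a covariate 2699 calls were left, but that covariate hardly moved the changes (median ratio 0.991). The pyruvate carboxylase difference was 1.61 in the sham arrays and 1.23 at 0 h (exact permutation p = 0.022, adjusted p = 0.11). With it alone as the covariate 1903 calls were left. Young 0 h replicate 3 had a pyruvate carboxylase difference of 2.29, above every sham array, and raised that 0 h mean. The other 0 h arrays lay at 0.80 to 1.12, below the lowest sham array at 1.24, while PH arrays reached 1.30. The actin and Gapdh differences were 0.06 and 0.05 higher in the sham arrays than at 0 h (exact permutation p = 0.408 and 0.452). A separate processing batch of the sham arrays also stays open and is consistent with 97.7% of the 0.5 h calls being shifted the same way at all 3 later sham times, against 52.0% in 20 simulations with no effect. It is also in line with a spike-in standard deviation of 0.112 in the sham arrays and 0.971 in the others, a ratio of 0.115, and a response peculiar to sham surgery was not tested.

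In old livers at 0.5 h after PH, replicate 3 had Fos at 10.75 and Jun at 8.38, against 4.48 and 7.45 in replicate 1 and 4.40 and 7.09 in replicate 2. An array batch marked by the low spike-in level of replicate 3 was tested through the relation to that level within the other groups. That relation predicted a gap of 0.07 (95% interval -0.16 to 0.41) in the mean of the immediate early list, where 0.95 was observed. For Fos alone, whose change fell from 1.06 to 0.14 with the spike-in covariate, it predicted 0.41 (-0.89 to 2.23) where 6.31 was observed. These values argue against an effect of the size seen within groups. A batch shared with the PH arrays of 1 and 2 h stays open, since their low level lay between groups, which this relation leaves out. A liver of a later time could not be told apart from a 0.5 h liver: 2 of the 3 genes Mt1, Mt2 and Atf3 lay below the lowest PH 1 h array (Mt1 8.24 against 11.36, Mt2 8.23 against 11.62), while Atf3 at 9.76 lay within the 1 h range of 9.08 to 10.28. Whether replicates 1 and 2 may be unoperated livers stayed open, with a median shift of 23 probe sets of 0.11 in replicate 1 and -0.032 in replicate 2, and 0.16 in replicate 3. An old 0 h array deviated by up to 0.37, more than any of these shifts, so this test could not tell operated from unoperated livers. Replicate 1 was far from the old 0 h arrays in inflammatory and metal-binding genes, with Mt1 at 13.10 against 6.87 to 9.28, Mt2 at 13.25 against 7.26 to 8.68, Lcn2 at 12.55 against 5.60 to 6.61 and Saa2 at 14.13 against 7.89 to 10.60, and so was old sham 0.5 h replicate 1 (13.09, 12.86, 10.47 and 12.74), while a true difference between old livers was not tested.

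The rhythmic genes Per2 and Noct and 1 Usp2 probe set rose in young livers at 0.5 h after PH, and Dbp, another such gene, was 2.09 higher without passing (limma adjusted p = 0.0568). A later time of day at collection than that of the 0 h livers could not be told apart from other explanations. Without the genes called, 5 evening-phase genes minus 5 genes of the opposite phase gave a mean 1.13 higher after PH than at 0 h, with all 3 PH arrays above all 3 control arrays, and its exact permutation p over the arrays of 0.1 is the smallest that 3 against 3 arrays can give. A response to liver removal could not be told apart either: the median of 7 evening-phase genes in old livers was 0.04, a ratio of 0.0395 to that of young livers, with a bootstrap interval over these genes, which are not independent, from -0.19 to 0.96. These genes include Per2 and Usp2, whose calls in young livers prompted the question and which raise the young median. Without the genes called, the medians were 0.23 in young and 0.04 in old livers. An age difference in the clock stays open and untested.

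The following results were singled out because a test of the difference between times or ages passed. The difference between PH and sham changed since 0.5 h at 2 probe sets by 1 h, those of Cpeb2 and Apob. It had changed at 64 probe sets by 2 h, with the difference rising for C9orf72, Rcan1 and Maff among others. It had changed at 196 probe sets by 4 h, with the difference rising for Mrap, Dusp6 and Cdkn1a among others. Within the sham arrays, 3 probe sets (Apob, Rcan1 and 1700017B05Rik) changed from 0.5 to 1 h. Between 0.5 and 2 h, 21 sham probe sets changed. Between 0.5 and 4 h, 286 sham probe sets changed, with Fkbp5 rising and Fos and G6pc falling. The PH response at 0.5 h differed with age at 1 probe set, that of Srsf5 (limma adjusted p = 0.00136). Over the 4 times, 1 Usp2 probe set differed with age in PH against sham (adjusted p = 0.00231).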

How the results depend on the processing

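The spike-in covariate, the fit with young 0 h replicate 3 and old PH 0.5 h replicate 3 left out together, the fit without sham arrays, PH against 0 h over both ages and the changes since 0.5 h were chosen after the data had been seen. Under these and the planned settings, 30 counts of probe sets were recomputed. Of 5828 alternative values of 232 named gene results, 5733 kept their direction and their side of the threshold, 88 were no longer past it, 5 newly passed and 2 reversed. Of 159 alternative values of 53 gene list results, 122 stayed on their side of the threshold, lists that never passed included, and 37 lost their call. With the estimated correlation, passing lists were left only at 1 and 2 h after PH against 0 h. These were immediate early genes and genes of gluconeogenesis and the glucocorticoid or cAMP response. Both reversals were Fos in old livers at 0.5 h after PH, at -1.04 without old PH 0.5 h replicate 3 and at -1.04 with that array and young 0 h replicate 3 left out together. Its range without 1 array was -1.04 to 2.13. With the replicate number as a block, the 1 h change of the PH to sham difference went from 2 probe sets to 1, and the other 29 counts stayed within 1.5 times. For the shifts given here the cause was not tested.

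With 1 probe set per gene, the counts were 1899 for PH against sham at 4 h, 13 for young PH against 0 h at 0.5 h, 2 for age at 0 h, and 1 and 0 for the F tests of age against 0 h and sham. With array weights, sham against 0 h gave 4358 at 0.5 h and 5905 at 4 h, young PH against 0 h gave 638, 873 and 2103 at 0.5, 1 and 2 h, and both ages gave 60, 925 and 2925. Array weights also gave 623 for age at 0 h, 13 and 2 for the F tests, 1, 113 and 473 for the change of the PH to sham difference by 1, 2 and 4 h, and 780 for the sham change by 4 h. With median centring, young and old PH at 0.5 h gave 16 and 1 and the F test against 0 h gave 1. With the dimmest probe sets left out, young PH at 0.5 h gave 15 and that F test 1. With trend and robust settings, that F test gave 1, the 1 h change of the PH to sham difference 1 and the sham change by 2 h 12. With the compared groups alone, young PH gave 50 and 122 at 0.5 and 1 h, old PH 1, 26 and 256 at 0.5, 1 and 2 h, both ages 0 and 224 at 0.5 and 1 h, and age at 0 h 7. That fit gave 3 for the F test against sham, 1 and 33 for the change of the PH to sham difference by 1 and 2 h, and 81 and 622 for the sham change by 2 and 4 h. With cross-hybridisation suffixes left out, young PH at 0.5 h gave 12, age at 0 h 4 and the F tests 1 and 2.

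With the spike-in covariate, young PH gave 29 and 20 at 0.5 and 1 h, old PH 1, 49 and 149 at 0.5, 1 and 2 h, both ages 51 and 495 at 1 and 2 h, and the change of the PH to sham difference 0 and 7 by 1 and 2 h. With the 2 arrays left out, young and old PH at 0.5 h gave 26 and 20, age at 0 h 9, the F tests 3 and 2, and the change of the PH to sham difference 5 and 166 by 1 and 2 h. Without the sham arrays, the age comparison over all conditions stayed within 1.5 times.

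Without 1 array at a time, PH against sham ranged from 2203 to 3609 at 0.5 h, 2175 to 4839 at 2 h and 1918 to 2881 at 4 h. Sham against 0 h ranged from 1369 to 2993, 2598 to 4565 and 1772 to 4181 at 0.5, 1 and 2 h. Young PH against 0 h ranged from 2 to 14, 33 to 66, 249 to 479 and 548 to 814, old PH from 0 to 23, 25 to 568, 315 to 705 and 1073 to 1585, and both ages from 2 to 22 and 169 to 782 at 0.5 and 1 h. Age at 0 h ranged from 6 to 16 and the F tests from 0 to 11 and 1 to 120. The change of the PH to sham difference ranged from 1 to 6, 15 to 161 and 58 to 227, and the sham change from 1 to 23, 5 to 14 and 98 to 241. Signal over background was not analysed here, and what dim probe sets limit was read only from leaving out the dimmest 25%.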

Other observations

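PH against 0 h over both ages, the changes since 0.5 h and the split counts for them were chosen after the data had been seen. At 2 h after PH, members of further lists passed in the mean of both ages. Of 18 circadian clock genes, 8 were higher and 2 lower than at 0 h (8 and 3 adjusted over the list alone, camera adjusted p = 0.0047, and adjusted p = 0.149 with an estimated correlation). Bhlhe40 rose by 1.69 ± 0.27 log2 units and the repressor gene Nr1d2 by 0.94 ± 0.24, while Arntl, a core activator of the clock, fell by 0.99 (SE 0.23). Nr1d2 gave 0.89 with the spike-in covariate (adjusted p = 0.12). Of 20 heat shock genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.056), with the small heat shock protein gene Hspb8 up by 0.73 ± 0.12. Of 12 p53 targets, 4 were higher and 0 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0361, and adjusted p = 0.287 with an estimated correlation), with Mdm2, which limits p53, up by 0.67 ± 0.08. At 4 h, heat shock genes had 3 higher and 5 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.634), and p53 targets 3 higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.425). The PH arrays of 2 h had the low spike-in signal.

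At 4 h after PH, the activin subunit gene Inhbb was 1.71 ± 0.12 above 0 h and the helix-loop-helix genes Id1 and Id3 were 1.13 ± 0.25 and 0.89 ± 0.23 above it, while Tsc22d1 fell by 1.93 (SE 0.29). Of 27 TGF-beta and activin genes, 9 were higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.385). Of 39 xenobiotic metabolism genes, 4 were higher and 10 lower (4 and 10 adjusted over the list alone, camera adjusted p = 0.157): Cyp2b10 rose by 1.86 ± 0.21, and Cyp3a25 fell by 0.73 (SE 0.13) and Fmo1 by 0.71 (SE 0.14). Of 16 lipogenesis genes, 3 were higher and 6 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.385), with Thrsp up by 2.18 ± 0.28 and the regulator gene Srebf1 falling by 0.84 (SE 0.13). Of 25 fatty acid oxidation and PPAR-alpha genes, 5 were higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.716), with Pdk4 up by 1.69 ± 0.26 and the lipid droplet gene Plin2 by 1.29 ± 0.16. Of 24 unfolded protein response genes, 3 were higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.385), with Herpud1 falling by 0.92 (SE 0.21). Of 20 endothelial markers, 5 were higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.512), with Thbd up by 1.31 ± 0.12 and Nos3 by 0.60 ± 0.08. The keratin genes Krt8 and Krt18 rose by 1.37 ± 0.22 and 1.38 ± 0.21, Krt18 by 1 of 2 probe sets, and the basement membrane collagen gene Col4a1 by 1.37 ± 0.17. Of 11 cholangiocyte markers, 2 were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.0467, and adjusted p = 0.385 with an estimated correlation). Of 25 stellate cell and fibroblast markers, 4 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0811, and adjusted p = 0.656 with an estimated correlation). Of 13 male-biased liver genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.0467, and adjusted p = 0.656 with an estimated correlation), with Hsd3b5 falling by 2.08 (SE 0.52). In the age comparison over all conditions, 0 of 37 cell cycle genes were higher and 3 lower in old livers (0 and 3 adjusted over the list alone, camera adjusted p = 0.269), with Mki67 at -0.18 ± 0.04 and Foxm1 at -0.11 ± 0.03, each by 1 of 2 probe sets.

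The counts were compared with those from other splits of the same arrays. The shares of splits were not adjusted for the number of counts compared. A share under 0.05 was the limit set beforehand for excluding chance. Where another split still gave as many probe sets, chance was left open here even under that limit. Of 100 splits, the real one included, only the real one gave as many probe sets for PH against sham at each time: 3631, 5402, 4329 and 2921 against highest others of 1703, 3529, 2103 and 947. The same held for sham against 0 h, with 2769, 4286, 3754 and 3887 against highest others of 1811, 3389, 2337 and 2376. It also held for age over all conditions (1109, highest other 37) and for PH against 0 h over both ages at 1, 2 and 4 h (462, 1592 and 2923, highest others 37, 551 and 1418). At 0.5 h, 3 of 100 splits gave 11 or more, with a highest of 41, so chance was not excluded there. For the change of the PH to sham difference, only the real split gave as many at 2 h (64, highest other 5). At 4 h, 2 of 100 splits gave as many as 196, with a highest of 321, and chance was not excluded. It was not excluded at 1 h, where 9 of 100 splits gave 2 or more and the highest gave 13. It was not excluded for the F test of age against sham, where 6 of 100 splits gave 1 or more and the highest gave 2. For the F test against 0 h, 100 of 100 splits gave 0 or more, and the highest gave 5.

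With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Young PH against 0 h gave 5, 71, 496 and 952 probe sets at the 4 times, with highest others of 3, 5, 4 and 6. Old PH gave 0, 201, 650 and 1850, with highest others of 12, 7, 0 and 1, and at 0.5 h 10 of 10 splits gave 0 or more. Age at 0 h gave 18, with a highest other of 1. The 18 splits of the sham arrays were also too few, with 3, 21 and 286 probe sets changed since 0.5 h and highest others of 14, 1 and 2.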
